A study of Mus musculus with 16 samples.

How the data were processed

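Gene expression was measured in the left ventricle of mice on one-colour Agilent arrays, 16 arrays in all. Per the labels, total RNA came from a section through the middle of the ventricle, was extracted with a kit for fibrous tissue and was turned into Cy3-labelled cRNA. The labels call the animals of a group biological repeats, so the spread between arrays includes that between mice. Groups were taken from the labels as genotype by condition, with 4 arrays and 2 males per group.

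Spot intensity values are the background-subtracted and detrended processed signal that the authors deposited from Agilent Feature Extraction 9.5.1.1, per the submitters' processing notes and the file headers. They are not normalized between arrays, and very low spots hold a surrogate value. The flags for signal well above background, saturation and outlier spots were set by the same software, per the file headers. The authors also deposited a table of log2 values for 22057 probes, with the normalization and the choice of probes not given in the sources used here. Its columns followed the log2 processed signal of the same array with r of at least 0.9996 across probes, which are not independent, and had medians between 9.95 and 9.99 and 1 shared maximum of 19.2. They differed from a quantile normalization of the same probes by a median of 0.00606 and at most by 3.39, after the median difference was removed. Their scale is thus log2 intensity, with no centring of genes.

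Each array held 43379 spots of non-control probes and 1639 control spots. Control spots and outlier spots were left out, saturated spots (at most 2 probes per array) were kept, and the 245 probes present on 10 spots each were averaged. This left 41174 probes. Of these, 22951 were named through their accession and 9768 through a symbol or synonym in a RefSeq gene table of assembly GRCm38.p6, and 8455 kept the name in the file.

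The log2 processed signal minus each array's 75th percentile was analysed. A probe was kept where it was well above background on at least 4 of the 16 arrays, and the probe with the highest mean stood for a gene, which gave 15669 genes. Limma 3.58.1 (lmFit, contrasts and eBayes) in R 4.3.3, with the package data.table at 1.17.8, fitted the 4 group means and sex over all 16 arrays, and a separate fit with a mean per group and sex gave the sex-by-TAC test. Calls are at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, two-sided. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. A gene that no array of a group showed well above background has only a lower bound of its fold, from the other group's mean and, per array of the dim group, the higher of the gene's own signal and the lowest signal well above background.

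The 37 gene lists, each with at least 5 measured genes, were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera compares a list with all other genes, so its direction is relative to them. Unless said otherwise, median, mean and test of a list had the same sign. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. That rule names Nos3, Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Pln, Col1a1, Col3a1, Postn and Ccn2 in the TAC and genotype comparisons and Xist, Ddx3y, Kdm5d, Eif2s3y and Uty between the sexes. It adds the 10 largest rises and falls among called genes in which all arrays of one group lay above all of the other, and, for the interactions, the 10 largest called in each direction. Where fewer than 3 genes passed, the 3 with the smallest p in each direction are given as not passing. It further adds up to 4 called members, by size, of each list that camera called or that had at least 3 called members. Some genes that the rule selects are not given here, among them smaller changes left out for length. Snrpn, Snurf, Snhg14, Peg3 and Snhg11 were taken as a set after their values were seen.

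Slide and scan day were read from the files. Slides 1 and 4 held baseline arrays and slides 2 and 3 TAC arrays, 4 arrays each, and slide 3 was scanned on a second day. Each slide held both genotypes and sexes, with males of NOS3-TG, females of NOS3-TG, males of WT and females of WT at positions 1, 2, 3 and 4. Within-slide correlation of the residuals was 0.0602. Genotype and sex results are therefore given also with slide as a block and within each slide.

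Alternatives were quantile normalization, normexp background correction (offset 50) of the mean and local background signals, the authors' values, no filter, a filter on all 16 arrays, the mean of all probes of a gene, array weights, an intensity trend of the variance, no sex term, the compared groups alone, slide and scan day as blocks, and each array left out in turn. Where the text gives a value with 1 array left out, it is the highest adjusted p over the arrays left out. Leaving out the 3 arrays with extreme shares above background, limma on each array's mean over a list, single arrays left out for lists, and for genotype slide as a random block and pairs of slide and sex as a block were chosen after seeing the data.

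The fit was tested on simulated data with 200 changed genes of 15669. At a log2 change of 1 it recovered 73% of them for TAC in WT, 78% for TAC in NOS3-TG, 79% for genotype at baseline, 71% for genotype after TAC, 88% over both conditions and 87.5% for sex. At 0.5 the shares were 28.5%, 35%, 25%, 30%, 57.5% and 60.5%. In 20 runs over 37 lists of genes simulated as independent, camera made 1 false call and found the shifted list in all 20. Correlated genes were not simulated.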

Results

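Messenger RNA of the left ventricle was measured on one-colour microarrays in 16 mice. The mice carried nitric oxide synthase 3 (Nos3, the endothelial enzyme that makes nitric oxide) under the alpha-myosin heavy chain promoter, which is active in cardiomyocytes, or were wild-type (WT) littermates. Mice of either genotype were left intact (baseline) or were examined 10 weeks after transverse aortic constriction (TAC), a surgical narrowing of the aorta that raises the pressure load of the left ventricle. Each of the 4 groups held 4 arrays, from 2 males and 2 females, and the transgenic mice are called NOS3-TG. The 75th percentile of the processed signal lay between 1053 and 1491 on all arrays. The share of probes well above background had a median of 52.5%. It was 44.8% on NOS3-TG baseline replicate 2, 46.2% on NOS3-TG TAC replicate 3 and 68.0% on NOS3-TG TAC replicate 4, so the arrays farthest from the median were all from NOS3-TG mice. The number of arrays limits the precision: the median standard error of a log2 difference between 2 groups was 0.13.

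The first comparison set WT TAC against intact WT hearts, so load cannot be told from surgery or slide. TAC raised the natriuretic peptide genes Nppb, by 2.94 ± 0.29 on the log2 scale (SE from limma, 4 arrays per group, adjusted p = 7.85e-05), and Nppa, by 2.06 ± 0.39 (adjusted p = 0.00264). Acta1, the skeletal alpha-actin that the loaded ventricle re-expresses, rose by 2.45 ± 0.33 (adjusted p = 0.000404), and Myh7, the beta-myosin heavy chain, by 0.88 ± 0.22 (adjusted p = 0.00973). Genes of connective tissue rose as well: Postn, a matricellular protein of activated fibroblasts, by 2.46 ± 0.48, Ccn2, the connective tissue growth factor, by 2.12 ± 0.38, and the collagen chains Col1a1 by 1.32 ± 0.25 and Col3a1 (adjusted p = 0.00387). Pln, the phospholamban that restrains the calcium pump of the sarcoplasmic reticulum, fell by 0.39 on the log2 scale (adjusted p = 0.0351), and the WT animals' own Nos3 rose by 0.41 ± 0.12 (adjusted p = 0.0195). In each of these genes except Col3a1 all 4 TAC arrays lay on one side of all 4 baseline arrays. The pump gene Atp2a2 (-0.28 ± 0.15, adjusted p = 0.194) and the alpha-myosin heavy chain gene Myh6 (-0.25 ± 0.12, adjusted p = 0.14) did not pass, and the other probe of Myh6 pointed the opposite way. With 1 array left out, the adjusted p was above 0.05 for Pln (0.118) without WT TAC replicate 4 and Nos3 (0.0572) without WT baseline replicate 1.

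By size, the rises included Lox, which crosslinks collagen (at least 7.53-fold higher, adjusted p = 0.000204). Where no array of a group was well above background, the fold is such a lower bound, set against the lowest signal among probes well above background, and other values given after a gene's symbol are log2 changes. Further rises were found for Pbp2 (at least 4.33-fold, with 3 of the 4 TAC arrays above background), the carboxylesterase Ces5a (at least 3.77-fold), the thyroid hormone activating deiodinase Dio2 (3.39), the stress cytokine Gdf15 (3.33), the matrix protein Cilp (3.28) and the nicotinamide riboside kinase Nmrk2 (3.27). The falls included those of the chemokine Ccl11 (at least 3.08-fold lower), the glycolytic regulator Pfkfb1 (-3.30), the water channel Aqp4 (at least 2.82-fold lower), Slc46a2 (at least 1.66-fold lower), the acyl-CoA thioesterase Acot1 (-2.98), Ces1d (-2.95), the lipid droplet protein Plin1 (at least 3.9-fold lower) and Acsm5 (-2.84). Each of these genes had all arrays of one group above all of the other. In the files the Lox probe A_51_P300493 lies on chromosome 18, 52894559 to 52894618 and the Nppb probe A_52_P559955 on chromosome 4, 146975497 to 146975556. The genome build of these positions is not given in the sources used here.

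Gene lists fixed beforehand grouped the changes. Of 24 measured genes of the hypertrophic fetal programme 18 rose and 1 fell (19 and 1 adjusted over the list alone), with camera adjusted p = 2.6e-10 and adjusted p = 0.0804 with an estimated correlation. Among them was the stretch-responsive Ankrd2 (2.36). Of 62 extracellular matrix genes 39 rose and 3 fell (43 and 3 adjusted over the list alone), with camera adjusted p = 3.92e-14 and adjusted p = 0.495 with an estimated correlation. Among them were Ltbp2 (2.87) and Mfap5 (2.47). Of 35 genes of TGF-beta signalling 17 rose and 3 fell (18 and 3 adjusted over the list alone), with camera adjusted p = 2.68e-05 and adjusted p = 0.495 with an estimated correlation. Higher were the ligands Tgfb2 (1.37) and Gdf6 (3.03, measured on 3 TAC arrays and 1 baseline array). Moving with these lists, of 22 fibroblast markers 8 rose and 2 fell (9 and 2 adjusted over the list alone), with camera adjusted p = 0.0489 and adjusted p = 0.591 with an estimated correlation. Higher were Meox1 (2.22) and Mfap4 (2.10) and lower Scara5 (-1.61). Of 36 cell cycle genes 26 rose and 1 fell (29 and 1 adjusted over the list alone), with camera adjusted p = 2.43e-12 and adjusted p = 0.495 with an estimated correlation. Among them were the mitotic kinases Cdk1 (at least 5.37-fold) and Bub1 (at least 2.09-fold) and the topoisomerase Top2a (at least 2.4-fold, above background on 3 TAC arrays). On leaving out 1 array, the adjusted p exceeded 0.05 for the fibroblast markers list (0.115) without WT baseline replicate 4.

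Called members of the energy metabolism lists were lower after TAC. Of 38 genes of fatty acid oxidation 28 fell (29 adjusted over the list alone), with camera adjusted p = 3.68e-11 and adjusted p = 0.495 with an estimated correlation. Among them were the uncoupling protein Ucp3 (-1.71) and the fatty acid transporter Slc27a1 (-1.19). Of 74 genes of oxidative phosphorylation 0 rose and 45 fell (1 and 57 adjusted over the list alone), with camera adjusted p = 2.25e-11 and adjusted p = 0.525 with an estimated correlation. Of 30 genes of the tricarboxylic acid cycle 21 fell (24 adjusted over the list alone), with camera adjusted p = 8.45e-08 and adjusted p = 0.52 with an estimated correlation. Of 23 metabolic transcription regulators 13 fell (14 adjusted over the list alone), with camera adjusted p = 0.000633 and adjusted p = 0.495 with an estimated correlation. Among them were the retinoid receptor Rxrg (-1.04), the thyroid hormone receptor Thrb (-0.85) and the coactivator Ppargc1a (-0.76). Of 32 potassium and sodium channel genes 1 rose and 12 fell (1 and 14 adjusted over the list alone), with camera adjusted p = 0.0012 and adjusted p = 0.495 with an estimated correlation. Lower were Kcnv2 (-2.34), Kcnd2 (-1.98), Kcnj3 (-1.70) and Kcnn2 (-1.53). Of 34 genes of calcium handling and contraction 2 rose and 8 fell (2 and 8 adjusted over the list alone), with camera adjusted p = 0.0266 and adjusted p = 0.591 with an estimated correlation. The calcium release channel Ryr2 was called at -0.66, but its other probe pointed the opposite way and normexp background correction turned its direction. Single omissions raised the adjusted p above 0.05 for the calcium handling and contraction list (0.075) and Ryr2 (0.145) without WT TAC replicate 4.

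Most called members of the lists that follow were higher. Of 28 macrophage and monocyte markers 15 rose (15 adjusted over the list alone), with camera adjusted p = 4.64e-07 and adjusted p = 0.495 with an estimated correlation. Among them was Cx3cr1 (1.71). Moving with them, of 36 cytokines and chemokines 12 rose and 4 fell (14 and 5 adjusted over the list alone), with camera adjusted p = 0.00315 and adjusted p = 0.495 with an estimated correlation. Of 34 interferon response genes 10 rose (12 adjusted over the list alone), with camera adjusted p = 1.86e-06 and adjusted p = 0.522 with an estimated correlation. Of 16 antigen presentation genes 4 rose (4 adjusted over the list alone), with Ctss at 0.75 and B2m at 0.60, although 1 of the 2 other B2m probes went the opposite way, and camera adjusted p = 0.0154 and adjusted p = 0.612 with an estimated correlation. Of 22 endothelial markers 7 rose (7 adjusted over the list alone), with camera adjusted p = 0.00233 and adjusted p = 0.495 with an estimated correlation. Among them was elastin, Eln (1.55). Of 31 genes of the unfolded protein response and heat shock 8 rose and 3 fell (8 and 3 adjusted over the list alone), with camera adjusted p = 0.000428 and adjusted p = 0.0804 with an estimated correlation. The adjusted p was over 0.05 with 1 array left out for the antigen presentation list (0.0782) without WT baseline replicate 4.

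Lists that camera did not call still had members past the threshold. As 4457 of all 15669 genes passed in this comparison, such counts alone do not set a list apart. Of 17 smooth muscle and pericyte markers 3 rose and 4 fell (3 and 5 adjusted over the list alone), with Lmod1 (-1.11), Myh11 (-1.07) and Abcc9 (-0.98) lower (camera adjusted p = 0.63). Acta2 was called at 0.87, with 3 of its 3 other probes opposite and a negative mean over all its probes. Of 25 immediate early genes 5 rose and 4 fell (5 and 4 adjusted over the list alone), with Egr3 (at least 3.35-fold) and Egr2 (1.84) higher and Nr4a1 (-1.37) lower (camera adjusted p = 0.289). Of 49 antioxidant genes 5 rose and 9 fell (5 and 9 adjusted over the list alone), with Gstt1 (-1.59) lower (camera adjusted p = 0.806). Of 35 genes of nitric oxide and cGMP signalling 9 rose and 7 fell (10 and 7 adjusted over the list alone), with the G protein regulator Rgs2 at -1.12 and the chaperone Hsp90aa1 at 0.87 (camera adjusted p = 0.549). Of 36 apoptosis and autophagy genes 8 rose and 6 fell (8 and 6 adjusted over the list alone), with the cell cycle inhibitor Cdkn1a at 1.76 (camera adjusted p = 0.0993). Of 32 renin-angiotensin and adrenergic genes 7 rose and 5 fell (7 and 5 adjusted over the list alone), with Edn3 at 1.46 and the alpha1-adrenergic receptor Adra1b at -1.40 (camera adjusted p = 0.587). Of 26 glycolysis genes 4 rose and 8 fell (4 and 8 adjusted over the list alone), such as Phkg1 (-1.78), with a camera adjusted p of 0.369. Of 33 hypoxia and angiogenesis genes 6 rose and 6 fell (8 and 6 adjusted over the list alone), such as Angpt1 (-1.54), with a camera adjusted p of 0.187. Of 27 complement and coagulation genes 5 rose and 2 fell (4 and 2 adjusted over the list alone), with a camera adjusted p of 0.0873.

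Of 26 cardiomyocyte markers 2 rose and 4 fell (2 and 1 adjusted over the list alone), with a camera adjusted p of 0.238. Of 12 lymphocyte markers 1 fell (1 adjusted over the list alone), with a camera adjusted p of 0.516. Of 8 granulocyte and mast cell markers none passed, nor did any adjusted over the list alone (camera adjusted p = 0.757), and of 9 sex-linked genes 1 fell (1 adjusted over the list alone), with a camera adjusted p of 0.971. Median, mean and test differed in sign for nitric oxide and cGMP signalling, oxidative stress and antioxidant genes, renin-angiotensin and adrenergic genes, hypoxia and angiogenesis and lymphocyte markers, which camera did not call. Limma called 4457 of 15669 genes at an adjusted p under 0.05, 1707 higher and 2750 lower, 815 of them by over 2-fold, and 6316 had an unadjusted p under 0.05 where chance gives 783. Leaving out WT TAC replicate 4 left 2911 genes, and scan day as a block left 2694. Of 143 called genes chosen for naming, 117 kept the call without any single array.

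**Figure D1:**
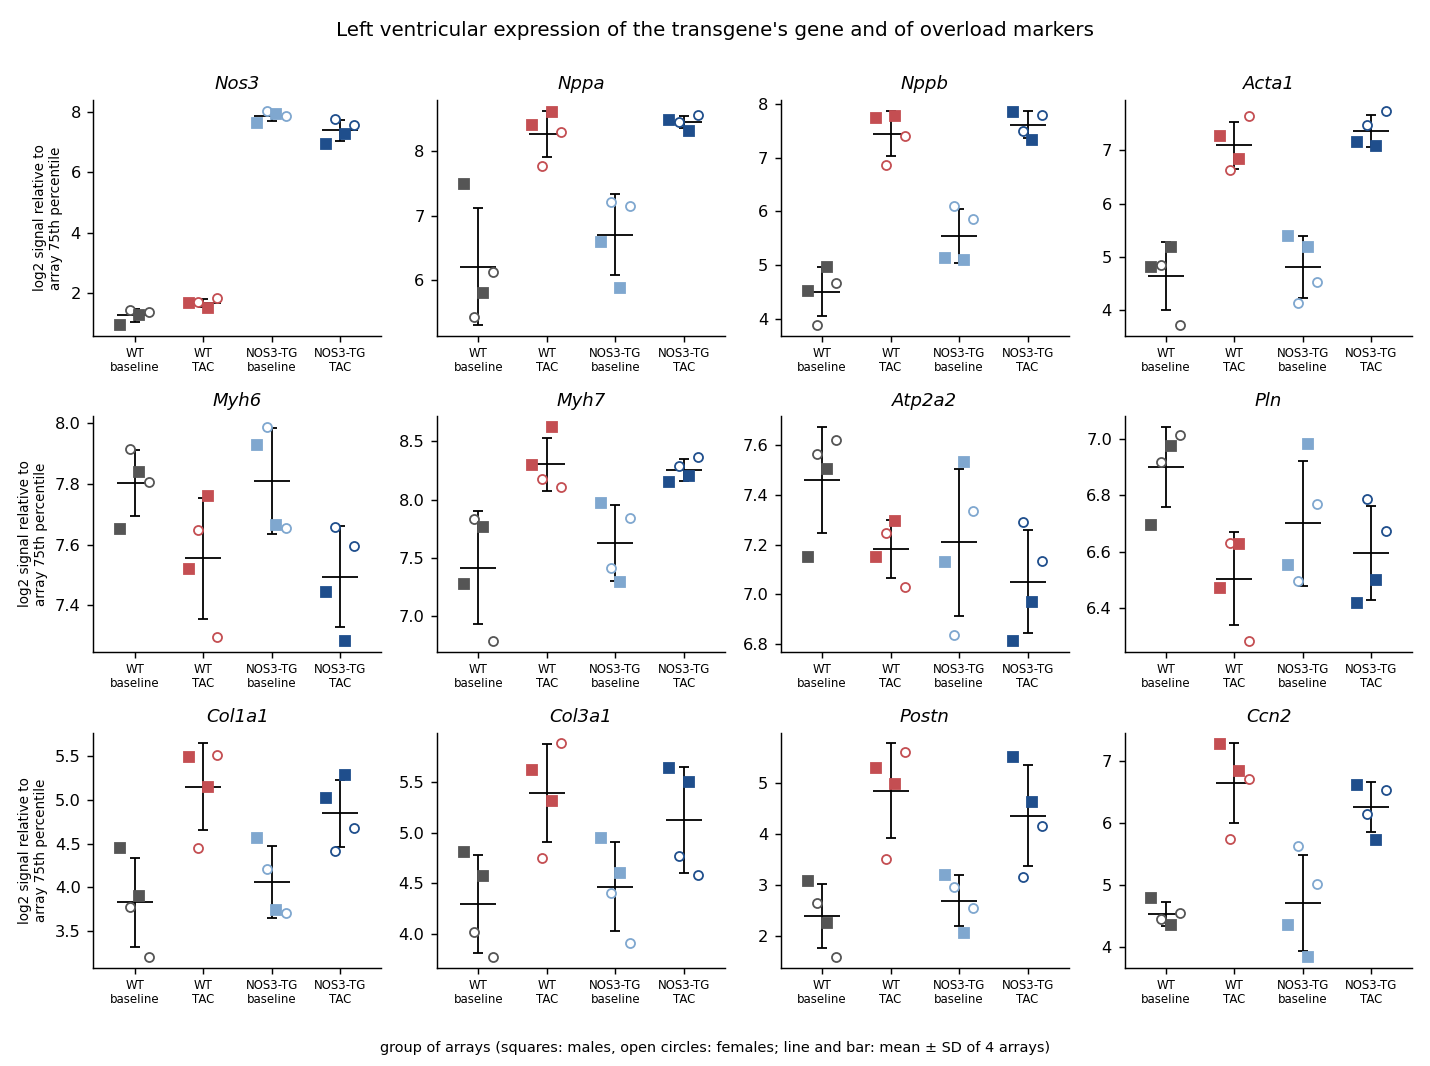
Log2 signal relative to each array's 75th percentile (vertical axes) of 12 genes in the 4 groups, with 1 point per array (squares males, open circles females) and a line and bar for the mean ± SD of 4 arrays. Nos3 stands at 1.28 ± 0.22 in WT baseline and 7.86 ± 0.17 in NOS3-TG baseline arrays, and Nppb rises from 4.51 ± 0.45 to 7.45 ± 0.42 with TAC in WT.

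The same was done for NOS3-TG ventricles. TAC raised Acta1 by 2.56 ± 0.33 (adjusted p = 0.000746), Nppb by 2.08 ± 0.29 (adjusted p = 0.0011) and Nppa by 1.75 ± 0.39 (adjusted p = 0.0144) on the log2 scale, with all 4 TAC arrays above all 4 baseline arrays, as for Ccn2, which rose by 1.56 ± 0.38 (adjusted p = 0.0197). Postn rose by 1.68 ± 0.48 (adjusted p = 0.0403) and Nos3, in these mice transgene and mouse gene together, fell by 0.48 on the log2 scale (adjusted p = 0.0207), although in both genes the arrays of the conditions overlapped. Col1a1 (0.79 ± 0.25, adjusted p = 0.0613), Col3a1 (0.66 ± 0.23, adjusted p = 0.0783, its other probe opposite), Myh7 (0.62 ± 0.22, adjusted p = 0.0817), Myh6 (-0.32 ± 0.12, adjusted p = 0.107), Atp2a2 (-0.16 ± 0.15, adjusted p = 0.542) and Pln (-0.11 ± 0.13, adjusted p = 0.63) did not pass. Calls lost with 1 array left out, by adjusted p, were Ccn2 (0.061) and Postn (0.119) without NOS3-TG TAC replicate 1 and Nos3 (0.0629) without NOS3-TG baseline replicate 3.

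The rises included those of Ces5a (at least 3.97-fold), Pbp2 (at least 4.07-fold), Nmrk2 (3.52), the protease Adamts20 (at least 3.31-fold), the steroidogenic regulator Star (at least 3.28-fold), the water channel Aqp8 (3.14) and Gdf15 (3.03). The falls included those of 2210407C18Rik (-3.25), Ccl11 (-2.84, measured on 1 TAC and 3 baseline arrays), Pfkfb1 (-2.48), Acot1 (-2.46), the proenkephalin gene Penk (-2.34) and the noncoding RNA Snhg11 (-2.33).

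Of 24 genes of the hypertrophic fetal programme 11 rose and 1 fell (16 and 1 adjusted over the list alone), with camera adjusted p = 1.57e-08 and adjusted p = 0.256 with an estimated correlation. Of 62 extracellular matrix genes 18 rose and 3 fell (28 and 3 adjusted over the list alone), with camera adjusted p = 6.78e-07 and adjusted p = 0.669 with an estimated correlation. Among them was Lox (2.35, measured on 1 baseline array). Beside them, of 22 fibroblast markers 3 rose and 2 fell (5 and 3 adjusted over the list alone), with Meox1 (1.80) and Pi16 (1.02) higher (camera adjusted p = 0.541). Of 35 genes of TGF-beta signalling 7 rose and 1 fell (11 and 1 adjusted over the list alone), with camera adjusted p = 0.026 and adjusted p = 0.669 with an estimated correlation. Of 38 genes of fatty acid oxidation 14 fell (24 adjusted over the list alone), with camera adjusted p = 6.63e-11 and adjusted p = 0.565 with an estimated correlation. Of 74 genes of oxidative phosphorylation 1 rose and 6 fell (1 and 1 adjusted over the list alone), with camera adjusted p = 5.46e-06 and adjusted p = 0.733 with an estimated correlation. Of 30 genes of the tricarboxylic acid cycle 3 fell (1 adjusted over the list alone), with camera adjusted p = 6.21e-05 and adjusted p = 0.669 with an estimated correlation. Of 23 metabolic transcription regulators 1 fell (0 adjusted over the list alone), with camera adjusted p = 0.0244 and adjusted p = 0.669 with an estimated correlation. Of 32 potassium and sodium channel genes 1 rose and 5 fell (2 and 8 adjusted over the list alone), with camera adjusted p = 0.00116 and adjusted p = 0.565 with an estimated correlation. Lower was Kcnj3 (-1.34). Of 34 genes of calcium handling and contraction 2 rose and 4 fell (2 and 4 adjusted over the list alone), with camera adjusted p = 0.0304 and adjusted p = 0.669 with an estimated correlation. With 1 array left out, the adjusted p was above 0.05 for the TGF-beta signalling list (0.156) without NOS3-TG baseline replicate 3 and the metabolic transcription regulators list (0.112) and the calcium handling and contraction list (0.112) without NOS3-TG TAC replicate 1.

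Of 34 interferon response genes 7 rose (12 adjusted over the list alone), with camera adjusted p = 2.77e-06 and adjusted p = 0.669 with an estimated correlation. Of 36 cell cycle genes 3 rose and 1 fell (6 and 1 adjusted over the list alone), with camera adjusted p = 3.64e-06 and adjusted p = 0.669 with an estimated correlation. The list mean was 0.49 and -0.15 on the male and -1.34 and -1.02 on the female TAC arrays, against -1.39 to -1.02 at baseline. Of 49 antioxidant genes 8 fell (8 adjusted over the list alone), with camera adjusted p = 0.0114 and adjusted p = 0.565 with an estimated correlation. Of 28 macrophage markers 3 rose and 1 fell (3 and 2 adjusted over the list alone), with a list mean of 0.03 and a camera adjusted p of 0.823. Acta2 was called at 1.30 and Tek at 0.27, but all other probes of both pointed the opposite way, and so did the means over their probes. On leaving out 1 array, the adjusted p exceeded 0.05 for the oxidative stress and antioxidant genes list (0.0555) without NOS3-TG baseline replicate 2 and Tek (0.111) without NOS3-TG TAC replicate 1.

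Limma called 1849 genes, 1012 higher and 837 lower, 405 by over 2-fold, and 4351 had an unadjusted p under 0.05. The count was 971 without NOS3-TG TAC replicate 4, 1102 without NOS3-TG TAC replicate 1, and 1085, 1142 and 1133 without NOS3-TG baseline replicates 1, 3 and 4. It was 401 without the 3 arrays farthest from the median share above background, and 756 with scan day as a block. The balance turned without NOS3-TG baseline replicate 2, to 768 higher and 1012 lower, and with array weights, to 1419 higher and 1783 lower. Of 116 called genes chosen for naming, 69 kept the call without any single array.

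The genes called after TAC in either genotype overlapped. In both, 704 genes were higher, where independent lists would share 110, and 688 were lower, where independent lists would share 147, while 2 were called in opposite directions. Of the 4457 genes called in WT, 4254 had the same sign in NOS3-TG mice, and 1809 of the 1849 called in NOS3-TG mice had the same sign in WT. Over all genes, which are not independent replicates, the log2 changes of the genotypes correlated with Pearson's r = 0.766. Changes computed from separate slides correlated with r between 0.239 and 0.563. Slides 1 and 4 held the baseline arrays and slides 2 and 3 the TAC arrays of both genotypes, so any effect of a slide enters both responses.

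**Figure D2:**
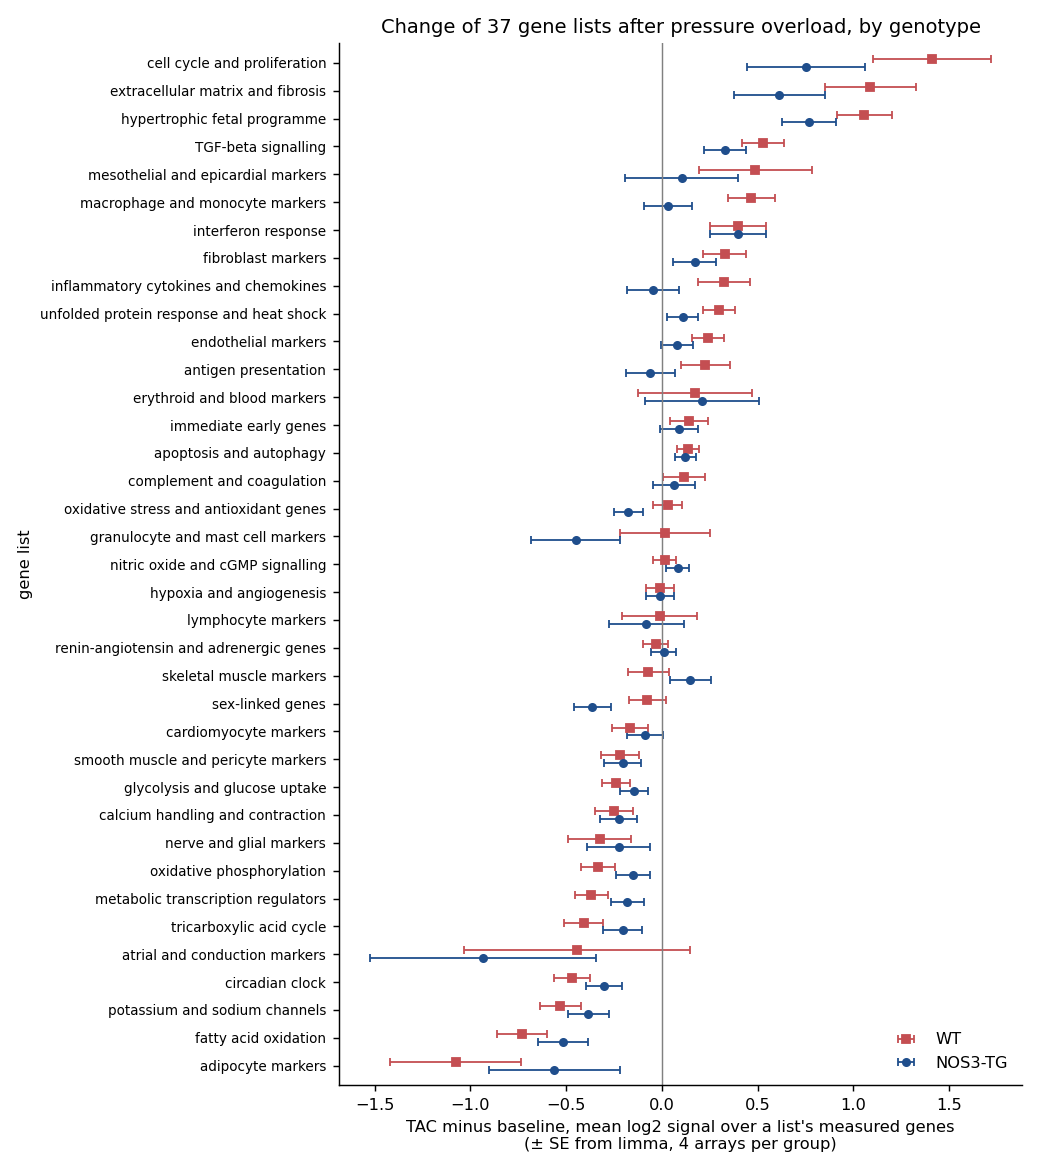
Change with TAC (log2, horizontal axis) of the mean signal of 37 gene lists, in WT (red squares) and NOS3-TG mice (blue circles), with bars for the SE from limma. The cell cycle list has a mean change of 1.41 in WT and 0.75 in NOS3-TG mice, the fatty acid oxidation list -0.73 and -0.52.

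The next comparison asked what the transgene changed in the unloaded ventricle. Nos3 was 95.9-fold higher in NOS3-TG than in WT baseline hearts (6.58 ± 0.12, adjusted p = 7.58e-13), with all 4 arrays of one group above all 4 of the other. Its probe A_51_P139651 lies on chromosome 5, 23424311 to 23424370. The labels do not give the species of the transgene's coding sequence, so this probe need not read the transgene and the mouse gene alike. Also higher were the glutathione transferases Gsta2 (3.74 ± 0.47, adjusted p = 0.00264) and Gsta1 (3.33 ± 0.44, adjusted p = 0.00396), the quinone reductase Nqo1 (1.00 ± 0.16, adjusted p = 0.0134), the sulfiredoxin Srxn1 (1.00) and Gclm (1.03), a subunit of the enzyme that begins glutathione synthesis. Gsta1 and Gsta2 are near-identical paralogs, so their values are uncertain as to which of them was measured. The Gsta2 probe A_52_P458682 lies on chromosome 9, 78408171 to 78408230 and the Nqo1 probe A_51_P424338 on chromosome 8, 105988683 to 105988742. Single omissions raised the adjusted p above 0.05 for Nqo1 (0.0664) without WT baseline replicate 4 and Gclm (0.0554) without NOS3-TG baseline replicate 2.

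Snhg11, a noncoding RNA, was at least 23.9-fold higher (adjusted p = 1.37e-05). The imprinted zinc finger gene Peg3 was higher by 2.97 ± 0.53 (adjusted p = 0.0303), and the imprinted transcripts Snurf by 1.89 ± 0.34 and Snhg14 by 1.86 ± 0.33 (adjusted p = 0.0318 for both). The Snhg11 probe A_51_P267933 lies on chromosome 2, 158126708 to 158126767. Mei1 was at least 3.09-fold higher, Krtap6-1 at least 3.97-fold, with its other probe opposite, and BC023105 by 2.56 on the log2 scale, with 1 WT array above background. Lower in NOS3-TG hearts were the orphan receptor Nr4a1 (-2.09 ± 0.24, adjusted p = 0.00208) and Fos (-1.80, measured on 3 NOS3-TG arrays), both of the immediate early response, the endothelial and myeloid receptor Cd93 (-1.45), the sarcomere protein Myom3 (-1.01) and Zfp296 (-0.71, on 3 NOS3-TG arrays). Nppb (1.04 ± 0.29, adjusted p = 0.155) and Nppa (0.50 ± 0.39, adjusted p = 0.622) did not pass, nor did Acta1 (0.16), Myh6 (0.01), Myh7 (0.21), Atp2a2 (-0.25), Pln (-0.20), Col1a1 (0.23), Col3a1 (0.17), Postn (0.30) and Ccn2 (0.18), of which Atp2a2 had the smallest adjusted p, 0.526. The adjusted p was over 0.05 with 1 array left out for Peg3 (0.107) without WT baseline replicate 4, Snurf (0.139), Snhg14 (0.139), Krtap6-1 (0.106) and BC023105 (0.129) without NOS3-TG baseline replicate 2 and Fos (0.0676) and Myom3 (0.139) without WT baseline replicate 2.

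Of 49 antioxidant genes 5 were higher (13 adjusted over the list alone), with camera adjusted p = 5.23e-13 and adjusted p = 0.0181 with an estimated correlation, the single list in this comparison whose call held with an estimated correlation. Of 34 interferon response genes 1 was higher (13 adjusted over the list alone), the called one being Ifit1 (1.26), with camera adjusted p = 2.15e-21 and adjusted p = 0.194 with an estimated correlation. Of 16 antigen presentation genes none passed over all genes, and 8 were higher adjusted over the list alone (camera adjusted p = 1.31e-10 and adjusted p = 0.245 with an estimated correlation). Of 36 cytokines and chemokines none passed over all genes, and 3 were higher adjusted over the list alone (camera adjusted p = 1.94e-08 and adjusted p = 0.194 with an estimated correlation). Markers of macrophages and lymphocytes moved with these lists. Of 28 macrophage markers 2 were higher (21 adjusted over the list alone), with camera adjusted p = 3.61e-28 and adjusted p = 0.0629 with an estimated correlation. Among them was Adgre1 (0.63). Of 12 lymphocyte markers none passed over all genes, and 5 were higher adjusted over the list alone, with camera adjusted p = 7.25e-07 and adjusted p = 0.194 with an estimated correlation. Of 27 complement and coagulation genes 1 was higher (5 adjusted over the list alone), with camera adjusted p = 0.00759 and adjusted p = 0.564 with an estimated correlation, but with a median of -0.02 against a mean of 0.08. Of 25 immediate early genes 0 were higher and 2 lower (1 and 9 adjusted over the list alone), with camera adjusted p = 0.0081 and adjusted p = 0.564 with an estimated correlation. Of 17 smooth muscle markers none passed over all genes, and 2 were lower adjusted over the list alone (camera adjusted p = 0.00406 and adjusted p = 0.494 with an estimated correlation). Calls lost with 1 array left out, by adjusted p, were Ifit1 (0.156) without WT baseline replicate 4, Adgre1 (0.113) and the complement and coagulation list (0.108) without NOS3-TG baseline replicate 2 and the immediate early genes list (0.0893) without NOS3-TG baseline replicate 1.

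No gene of 7 further lists that camera called passed over all genes, and 1 cell cycle gene was lower adjusted over the list alone. List means were above 0 for cell cycle (0.31, camera adjusted p = 0.000274 and adjusted p = 0.787 with an estimated correlation), extracellular matrix (0.10, camera adjusted p = 0.025 and adjusted p = 0.787 with an estimated correlation) and fetal programme genes (0.16, camera adjusted p = 0.0421 and adjusted p = 0.564 with an estimated correlation). They were below 0 for oxidative phosphorylation (-0.21), fatty acid oxidation (-0.31), the tricarboxylic acid cycle (-0.25) and hypoxia (-0.18), with camera adjusted p values of 1.87e-13, 8.4e-08, 2.4e-08 and 0.0331, and each with adjusted p = 0.564 with an estimated correlation. Without NOS3-TG baseline replicate 2 the matrix list's mean was -0.04, so its direction rested on 1 array. With 1 array left out, the adjusted p was above 0.05 for the matrix (0.852) and hypoxia lists (0.108) without NOS3-TG baseline replicate 2. It was 0.328 for the fetal programme list without WT baseline replicate 4.

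Limma called 65 genes, 52 higher and 13 lower, 32 by over 2-fold, and 1926 had an unadjusted p under 0.05. With slide as a block there were 109, and within slides 1 and 4 alone 9 and 2. The count was 26 without NOS3-TG baseline replicate 2, 31 without replicate 3 and 39 without replicate 4 of that group, and 41, 28, 32 and 26 without WT baseline replicates 1, 2, 3 and 4. Without the 3 arrays farthest from the median share above background it was 24. Of 27 called genes chosen for naming, 9 kept the call without any single array, namely Nos3, Snhg11, Gsta1, Gsta2, Srxn1, Mei1, Nr4a1, Cd93 and Zfp296.

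The genotypes were then compared after TAC. Nos3 was 51.7-fold higher in NOS3-TG hearts (5.69 ± 0.12, adjusted p = 5.05e-12), Snhg11 at least 4.09-fold (adjusted p = 0.00197), Gsta2 by 2.94 ± 0.47 on the log2 scale (adjusted p = 0.0206) and Gsta1 by 2.74 ± 0.44 (adjusted p = 0.0214), each with all arrays of one group above all of the other. BC023105 (at least 3.08-fold), Mei1 (at least 2.05-fold, on 3 arrays), 1700020L24Rik (1.39), Snrpn (1.39), which lies in the imprinted region of Snurf, the interferon-inducible Ifi27 (1.06) and the glutathione transferase Gstm2 (0.90) were higher too. Lower genes included Cd93 (-1.07 ± 0.17, adjusted p = 0.0214), Zfp296 (-0.79) and Gpc6 (-0.64, measured on 3 NOS3-TG arrays). None of the other fixed marker genes passed in limma: Nppa (0.18), Nppb (0.17), Acta1 (0.27), Myh6 (-0.06), Myh7 (-0.05), Atp2a2 (-0.13), Pln (0.09), Col1a1 (-0.30), Col3a1 (-0.27), Postn (-0.49) and Ccn2 (-0.38), with a smallest adjusted p of 0.705 for Col3a1. Single omissions raised the adjusted p above 0.05 for Gsta2 (0.0757), Gsta1 (0.0835), 1700020L24Rik (0.0757), Snrpn (0.0644), Gstm2 (0.0917) and Gpc6 (0.139) without NOS3-TG TAC replicate 4, BC023105 (0.0773) and Ifi27 (0.0683) without WT TAC replicate 1 and Mei1 (0.0541), Cd93 (0.0798) and Zfp296 (0.0508) without NOS3-TG TAC replicate 2.

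Of 34 interferon response genes 1 was higher (19 adjusted over the list alone), at a list mean of 0.51, with camera adjusted p = 9.16e-15 and adjusted p = 0.292 with an estimated correlation. With them, of 12 lymphocyte markers none passed over all genes, and 3 were higher adjusted over the list alone (camera adjusted p = 0.00389 and adjusted p = 0.491 with an estimated correlation). Of 28 macrophage markers none passed, nor did any adjusted over the list alone (list mean 0.17, camera adjusted p = 0.0116 and adjusted p = 0.867 with an estimated correlation). Of 49 antioxidant genes 2 were higher (6 adjusted over the list alone), with camera adjusted p = 0.00389 and adjusted p = 0.292 with an estimated correlation. Of 25 immediate early genes none passed over all genes, and 6 were lower adjusted over the list alone, at a list mean of -0.42 (camera adjusted p = 3.44e-10 and adjusted p = 0.186 with an estimated correlation). Of 17 smooth muscle markers none passed over all genes, and 5 were lower adjusted over the list alone (camera adjusted p = 0.000109 and adjusted p = 0.292 with an estimated correlation). In 6 further lists camera called lower no member passed, over all genes or adjusted over the list alone. These were endothelial markers (list mean -0.26, camera adjusted p = 2.65e-07) and hypoxia genes (-0.18, 0.000537), each with adjusted p = 0.292 with an estimated correlation. Extracellular matrix (-0.38, 6.41e-08) and TGF-beta genes (-0.16, 0.00405) each had adjusted p = 0.537 with an estimated correlation. The others were cell cycle (-0.35, camera adjusted p = 0.00287 and adjusted p = 0.89 with an estimated correlation) and unfolded protein genes (-0.10, camera adjusted p = 0.0116 and adjusted p = 0.29 with an estimated correlation). For cell cycle genes the mean was -0.02 and camera's direction turned without WT TAC replicate 4. The adjusted p was over 0.05 with 1 array left out for the lymphocyte markers list (0.119), the macrophage and monocyte markers list (0.622) and the oxidative stress and antioxidant genes list (0.0628) without WT TAC replicate 2 and the TGF-beta signalling list (0.178), the cell cycle and proliferation list (0.954) and the unfolded protein response and heat shock list (0.0624) without WT TAC replicate 4.

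Limma called 44 genes, 40 higher and 4 lower, 21 by over 2-fold, and 1922 had an unadjusted p under 0.05. On the authors' deposited values 57 were higher and 15 lower, a share of 79.2% higher against 90.9%. With slide as a block there were 74, and within slides 2 and 3 alone 1 each. The count was 2 without NOS3-TG TAC replicate 2, 7 without replicate 4 and 29 without replicate 1 of that group, and 6 without WT TAC replicate 1. Without the 3 arrays farthest from the median share above background it was 3. Of 16 called genes chosen for naming, Nos3 and Snhg11 kept the call without any single array. Of the 65 genes called at baseline, 63 had the same sign after TAC, and 16 were called higher and 2 lower in both, where independent lists would share 0.133 and 0.00332. Over all genes, which are not independent, r was 0.348, and it lay between 0.0844 and 0.31 for pairs of separate slides.

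**Figure D3:**
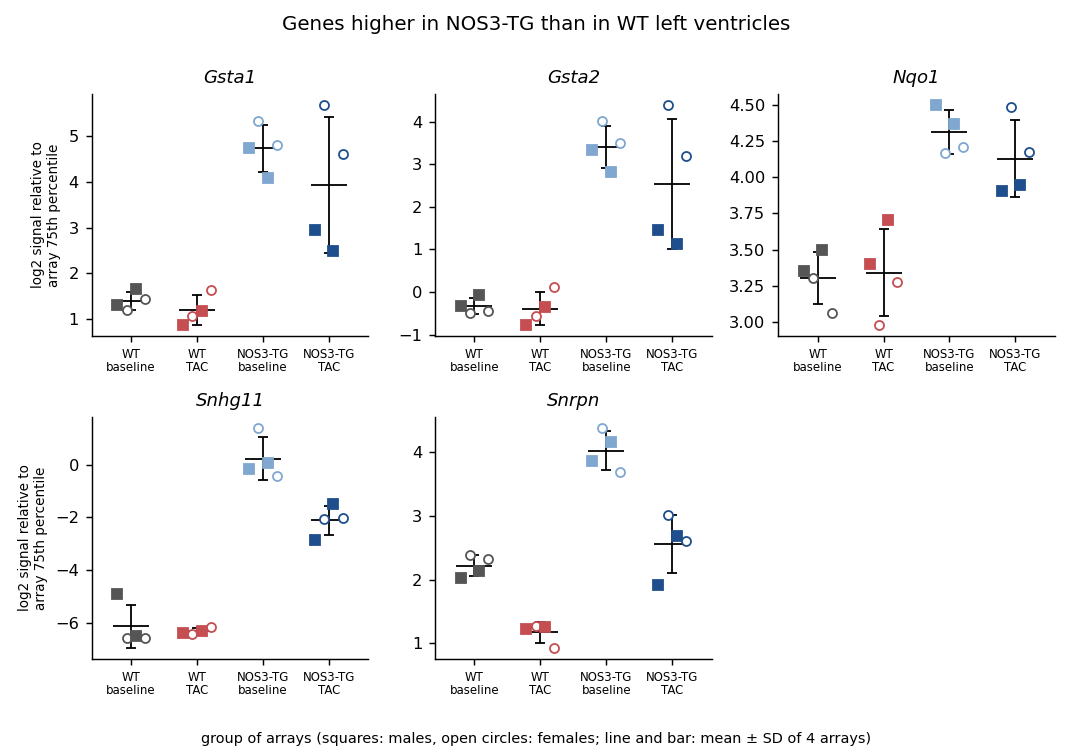
Log2 signal relative to each array's 75th percentile (vertical axes) of Gsta1, Gsta2, Nqo1, Snhg11 and Snrpn in the 4 groups, with 1 point per array (squares males, open circles females) and a line and bar for the mean ± SD of 4 arrays. Gsta2 stands at -0.33 ± 0.19 in WT baseline and 3.41 ± 0.49 in NOS3-TG baseline arrays.

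Whether the transgene altered the response to TAC was tested by the interaction of genotype and TAC. The log2 changes with TAC of Nppb differed by -0.87 ± 0.41 between NOS3-TG and WT mice, those of Postn by -0.78 ± 0.68, of Ccn2 by -0.56 ± 0.53 and of Col1a1 by -0.53 ± 0.36. None of them passed (smallest adjusted p = 0.679, for Nppb). Nor did Nppa (-0.31), Acta1 (0.11), Myh6 (-0.07), Myh7 (-0.26), Atp2a2 (0.12), Pln (0.29) and Col3a1 (-0.44). The genes with the smallest p did not pass either: Ier5, an immediate early gene (-1.08 ± 0.16, adjusted p = 0.242), Mafg, a small Maf transcription factor (-0.60 ± 0.12, adjusted p = 0.655), Nos3 (-0.89 ± 0.17, adjusted p = 0.622), the ryanodine receptor Ryr3 (1.43 ± 0.23, adjusted p = 0.242), and Cd247 and Clec12b (adjusted p = 0.655 for both), for which no size is given, as no WT TAC array showed them above background. Camera called 20 lists with the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.236, and limma on list means per array called 0 (smallest adjusted p = 0.476). Limma called 0 genes, with 1166 at an unadjusted p under 0.05 where chance gives 783. It called 0 also with slide as a block and within each pair of slides. Without NOS3-TG baseline replicate 1 it called 1, and 0 in the other omissions. In a simulation of this comparison over 15669 genes, 58.5% of true interactions of 1 on the log2 scale were called, and 2% of those of 0.5.

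Over both conditions together, Nos3 was higher in NOS3-TG hearts by 6.14 ± 0.08 (8 against 8 arrays, adjusted p = 2.04e-14 in limma). Also higher were Snhg11 (at least 9.87-fold), Gsta2 (3.34), Gsta1 (3.03), BC023105 (2.67, measured on 1 of 8 WT arrays), Mei1 (at least 2.52-fold, on 7 of 8 NOS3-TG arrays), Krtap6-1 (at least 3.2-fold, its other probe opposite), 1700020L24Rik (1.51) and the interferon-induced GTPase Igtp (1.26). Lower were Cd93 (-1.26 ± 0.12, adjusted p = 0.000223), Zfp296 (-0.75, on 6 of 8 NOS3-TG arrays) and the cyclic AMP sensor Rapgef3 (-0.63). All arrays of one genotype lay above all of the other in each of these genes. Nppb (0.60 ± 0.20, adjusted p = 0.16) did not pass, nor did the other fixed marker genes.

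Of 49 antioxidant genes 12 were higher and 0 lower (19 and 1 adjusted over the list alone), with camera adjusted p = 2.54e-09 and adjusted p = 0.0627 with an estimated correlation. Among them were Nqo1 (0.90 ± 0.11, adjusted p = 0.00127), Gsta4 (0.82) and the aldehyde oxidase Aox1 (0.78). Of 34 interferon response genes 11 were higher (25 adjusted over the list alone), with camera adjusted p = 9.8e-25 and adjusted p = 0.165 with an estimated correlation. Among them were Ifit1 (1.22), Usp18 (1.16) and Ifit3 (1.11). Moving with them, of 28 macrophage markers 5 were higher (19 adjusted over the list alone), with camera adjusted p = 1.08e-17 and adjusted p = 0.165 with an estimated correlation. Among them was Adgre1 (0.48). Of 12 lymphocyte markers 3 were higher (5 adjusted over the list alone), with camera adjusted p = 1.14e-06 and adjusted p = 0.167 with an estimated correlation. Among them were the natural killer and T cell genes Klrd1 (at least 1.53-fold, on 6 of 8 NOS3-TG arrays), Nkg7 (1.12, on 7 of 8 WT arrays) and Il2rb (0.87). Of 36 cytokines and chemokines 2 were higher (4 adjusted over the list alone), with Ccl5 (1.33) the larger, with camera adjusted p = 0.00252 and adjusted p = 0.533 with an estimated correlation. Of 16 antigen presentation genes none passed over all genes, and 2 were higher adjusted over the list alone (camera adjusted p = 5.9e-07 and adjusted p = 0.418 with an estimated correlation). Of 25 immediate early genes 6 were lower (13 adjusted over the list alone), with camera adjusted p = 6.58e-08 and adjusted p = 0.165 with an estimated correlation. Among them were Nr4a1 (-1.47), Fos (-1.33, on 6 of 8 NOS3-TG arrays) and the phosphatase Dusp1 (-0.71). Moving with these, of 17 smooth muscle and pericyte markers 3 were lower (5 adjusted over the list alone), with camera adjusted p = 2.86e-05 and adjusted p = 0.17 with an estimated correlation. Among them were Myh11 (-0.90), the receptor Notch3 (-0.45) and the myosin kinase Mylk (-0.37). Calls lost with 1 array left out, by adjusted p, were Klrd1 (0.0507) without WT baseline replicate 2, Nkg7 (0.0714) without WT baseline replicate 3, Il2rb (0.061) without WT baseline replicate 4, the inflammatory cytokines and chemokines list (0.06) without WT TAC replicate 2 and Myh11 (0.0528) without WT TAC replicate 1.

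Camera also called lower oxidative phosphorylation (list mean -0.12, camera adjusted p = 2.15e-08), fatty acid oxidation (-0.21, 4.91e-06) and the tricarboxylic acid cycle (-0.14, 1.92e-05), each with adjusted p = 0.778 with an estimated correlation. Lower too were endothelial markers (-0.18, camera adjusted p = 0.000135 and adjusted p = 0.418 with an estimated correlation) and hypoxia (-0.18, camera adjusted p = 0.000213 and adjusted p = 0.277 with an estimated correlation). Of 26 cardiomyocyte markers 1 was lower (1 adjusted over the list alone), the titin-binding Myom1 (-0.29), with camera adjusted p = 0.0499 and adjusted p = 0.877 with an estimated correlation. Limma called 325 genes, 232 higher and 93 lower, 66 by over 2-fold, and 2554 had an unadjusted p under 0.05. With slide as a block there were 335, and within slides 1, 2, 3 and 4 alone 9, 1, 1 and 2. The count was 205 without WT baseline replicate 4, 189 without WT baseline replicate 2, 210 without WT TAC replicate 1 and 208 without NOS3-TG baseline replicate 4, and 77 without the 3 arrays farthest from the median share above background. Of 41 called genes chosen for naming, 27 kept the call without any single array. With 1 array left out, the adjusted p was above 0.05 for Myom1 (0.0739) without WT baseline replicate 4 and the cardiomyocyte markers list (0.342) without WT TAC replicate 3.

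The design held both sexes, so males were compared with females over all groups (8 against 8 arrays). The Y-linked genes Eif2s3y (at least 64.3-fold), Ddx3y (at least 49.1-fold) and Kdm5d (at least 7.53-fold) were higher in males, and Xist, the noncoding RNA of the inactive X chromosome, was at least 54.4-fold higher in females (adjusted p = 7.91e-11). Its probe A_51_P145453 lies on chromosome X, 98790940 to 98790999. Uty was not measured here. The X-linked genes Kdm5c (-0.85 ± 0.07, adjusted p = 3.36e-05), Kdm6a (-0.78) and Eif2s3x (-0.72) were lower in males, although 1 of the 2 other Eif2s3x probes and the mean over its probes pointed the opposite way. Among further genes, the fatty acid desaturase Scd4 (1.67), Slc41a3 (1.25), the urea transporter Slc14a1 (1.11), Il17re (1.02) and the cold-inducible RNA-binding protein Rbm3 (0.87) were higher in males. The chaperone genes Hsph1 (-0.76) and Dnaja1 (-0.54), and Lin7a (-0.59) were lower in males. On leaving out 1 array, the adjusted p exceeded 0.05 for Scd4 (0.07) without NOS3-TG TAC replicate 3 and Slc14a1 (0.0501) and Lin7a (0.052) without NOS3-TG TAC replicate 2.

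Of 9 sex-linked genes 3 were higher and 5 lower (3 and 5 adjusted over the list alone), with a median of -0.53 and a mean of 1.07 (camera adjusted p = 0.23). Of 31 genes of the unfolded protein response and heat shock 1 was lower (8 adjusted over the list alone), with camera adjusted p = 0.000718 and adjusted p = 0.123 with an estimated correlation. Of 62 extracellular matrix genes 2 were higher and 0 lower (6 and 1 adjusted over the list alone), the membrane protease Mmp14 (0.85) and Thbs2 (0.47), with camera adjusted p = 3.31e-06 and adjusted p = 0.773 with an estimated correlation. Of 28 macrophage markers 2 were higher and 1 lower (5 and 2 adjusted over the list alone), with camera adjusted p = 0.000641 and adjusted p = 0.773 with an estimated correlation. Higher were Cx3cr1 (1.18) and Ccr2 (1.08) and lower Lyve1 (-0.74). Of 36 cytokines and chemokines 1 was higher and 1 lower (7 and 2 adjusted over the list alone), with camera adjusted p = 0.000715 and adjusted p = 0.773 with an estimated correlation. Moving with these lists, of 11 erythroid and blood markers none passed over all genes, and 4 were higher adjusted over the list alone, at a list mean of 0.67 (camera adjusted p = 0.00038 and adjusted p = 0.773 with an estimated correlation). In 6 further lists that camera called no member passed over all genes, and 2 fetal programme and 2 granulocyte genes were higher adjusted over the list alone. Higher in males by camera were cell cycle (list mean 0.41, camera adjusted p = 4.52e-06), antigen presentation (0.19, 0.000641), fetal programme (0.23, 0.0246) and granulocyte genes (0.45, 0.035), each with adjusted p = 0.773 with an estimated correlation. Lower were oxidative phosphorylation (-0.07, camera adjusted p = 0.000481 and adjusted p = 0.896 with an estimated correlation) and antioxidant genes (-0.08, camera adjusted p = 0.0355 and adjusted p = 0.773 with an estimated correlation). Single omissions raised the adjusted p above 0.05 for Mmp14 (0.0917), Cx3cr1 (0.0861), Ccr2 (0.101) and Lyve1 (0.0833) without NOS3-TG TAC replicate 2, Thbs2 (0.0792) without NOS3-TG TAC replicate 1, the hypertrophic fetal programme list (0.188) and the granulocyte and mast cell markers list (0.157) without WT TAC replicate 2 and the oxidative stress and antioxidant genes list (0.0937) without NOS3-TG baseline replicate 2.

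Limma called 208 genes, 113 higher and 95 lower in males, 25 by over 2-fold, and 2495 had an unadjusted p under 0.05. With slide as a block there were 217, and within slides 1, 2, 3 and 4 alone 4, 42, 9 and 4. Of the 16 arrays, all but NOS3-TG baseline replicate 3 moved the count by over 1.5 times. Without WT TAC replicates 1, 2, 3 and 4 it was 319, 93, 68 and 550, and without WT baseline replicates 1, 2, 3 and 4 it was 103, 117, 87 and 85. Without NOS3-TG TAC replicates 1, 2, 3 and 4 it was 85, 67, 95 and 119, and without NOS3-TG baseline replicates 1, 2 and 4 it was 89, 134 and 113. It was 24 without the 3 arrays farthest from the median share above background. The balance turned with array weights (322 higher and 421 lower) and the mean of all probes (93 and 94), and without 4 single arrays, among them NOS3-TG baseline replicate 2 (53 higher and 81 lower), and was even without the 3 arrays (12 and 12). Of 29 called genes chosen for naming, 15 kept the call without any single array.

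Whether males and females responded differently to TAC was tested over both genotypes, with values as the log2 change in males minus that in females. The genes with the smallest p, none of which passed, were Podn, a matrix proteoglycan with the more positive change in males (adjusted p = 0.119), the adhesion molecule Ncam1 (1.08 ± 0.16), Prkag2, a subunit of AMP-activated kinase (0.93 ± 0.13), the calcium pump Atp2b3 (-2.04 ± 0.26), the potassium channel Kcnj4 (-1.50 ± 0.23) and Ugp2, which makes the substrate of glycogen synthesis (-0.71 ± 0.10). Limma called 0 of 15668 genes, with a smallest adjusted p of 0.119, and 1776 had an unadjusted p under 0.05. Leaving out WT baseline replicate 4 gave 129 genes, WT TAC replicate 4 gave 116, NOS3-TG baseline replicate 4 gave 94, WT TAC replicate 2 gave 5, WT TAC replicate 3 gave 3 and NOS3-TG TAC replicate 1 gave 1, while each other omission gave 0. Camera called 15 lists with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.816), and limma on list means per array called 0.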

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

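Leaving out the 3 NOS3-TG arrays with extreme shares above background, and limma on list means per array, were chosen after the data were seen, and the other tests of this part were fixed before their results.

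Some arrays stood far from the other 3 of their group in the mean log2 signal of a gene list, by the ratio of their gap to the range of the group. Of 216 groups of 4 checked, 17 passed the critical ratio, where chance marks about 1 in 20. In WT baseline hearts, calcium handling genes had replicate 4 at 4.38 against 4.65 to 4.67 (ratio 0.93), fatty acid oxidation replicate 4 at 5.14 against 4.89 to 4.92 (ratio 0.88) and the interferon response replicate 4 at 0.31 against 0.48 to 0.51 (ratio 0.842). The same group had complement and coagulation with replicate 1 at 0.99 against 0.86 to 0.88 (ratio 0.856) and mesothelial markers with replicate 1 at -1.26 against -2.30 to -2.25 (ratio 0.956). Among NOS3-TG baseline hearts, macrophage markers had replicate 1 at 0.405 against 0.556 to 0.562 (ratio 0.956) and the interferon response replicate 1 at 0.69 against 1.01 to 1.07 (ratio 0.833). There, replicate 2 stood apart in endothelial markers (ratio 0.854), erythroid markers (0.887) and renin-angiotensin and adrenergic genes (0.894), replicate 3 in atrial and conduction markers (0.945) and replicate 4 in immediate early genes (0.857). After TAC in WT, replicate 2 had low macrophage (0.872), antigen presentation (0.884) and granulocyte markers (0.888), replicate 3 low smooth muscle markers (0.905), and replicate 4 the lowest share of probes above background (0.855).

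The TAC response of 20 lists differed between the genotypes by camera with the preset correlation, and none did with an estimated correlation (smallest adjusted p = 0.236) or by limma on list means (smallest adjusted p = 0.476). The mean log2 difference, NOS3-TG minus WT, was -0.66 for the cell cycle, -0.47 for extracellular matrix, -0.47 for granulocyte markers, -0.43 for macrophage markers, -0.38 for mesothelial markers, -0.37 for cytokines, -0.29 for antigen presentation, -0.29 for the fetal programme, -0.29 for sex-linked genes, -0.21 for antioxidant genes, -0.20 for TGF-beta signalling, -0.19 for the unfolded protein response, -0.16 for endothelial markers, -0.16 for fibroblast markers, -0.0537 for complement and -0.0523 for immediate early genes. It was 0.21 for fatty acid oxidation, 0.20 for the tricarboxylic acid cycle, 0.19 for metabolic regulators and 0.18 for oxidative phosphorylation. Between males and females 15 lists differed in the same way, and none with an estimated correlation (smallest adjusted p = 0.816) or by list means (smallest adjusted p = 0.354). The difference in TAC response, male minus female, was 1.56 for atrial markers, 0.51 for the cell cycle, 0.39 for extracellular matrix, 0.38 for nerve and glial markers, 0.38 for complement, 0.33 for macrophage markers, 0.28 for cytokines, 0.27 for the interferon response, 0.25 for antigen presentation and 0.12 for immediate early genes. It was -0.28 for the circadian clock, -0.18 for hypoxia, -0.16 for metabolic regulators, -0.11 for the tricarboxylic acid cycle and -0.0917 for oxidative phosphorylation.

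Over the 5832 genes called in the mean TAC response, the change was smaller in NOS3-TG than in WT mice for 72.5%, with a median interaction, signed by the direction of the response, of -0.14 (from -0.21 to -0.08 with single arrays left out). The tables argue against the 3 NOS3-TG arrays with extreme shares above background as the cause, since the median was -0.10 without them (over 4800 genes), and against compression near the background, since it was -0.13 over the 5133 genes well above background on all 16 arrays. Chance assignment of animals to the genotypes stays open: a two-sided exact permutation test over 1296 assignments gave p = 0.0864. The signed genotype difference of these genes was 0.09 at baseline and -0.04 after TAC, so the interaction may come from a baseline difference, a smaller response, or both. Whether load was milder in NOS3-TG hearts was not tested, as the degree of constriction was not used here.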

How the results depend on the processing

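Leaving out 3 arrays, limma on list means, single arrays left out for lists, and for genotype the random slide block and pairs of slide and sex, were chosen after the data were seen, and the other settings before. Over 5694 pairs of a named gene and an alternative other than within-slide fits and single omissions, 4944 kept direction and side of the threshold. Another 718 lost the call in the same direction, 6 gained it, and 21 uncalled and 5 called values turned direction. Within slides 166 of 522 pairs kept direction and side of the threshold, uncalled pairs included. Another 329 lost the call in the same direction, and 27 uncalled values turned direction. With single arrays left out, 3471 of 4320 pairs kept both, 792 lost the call, 20 gained it and 37 uncalled values turned direction. Direction turned for Ryr2 after TAC in WT with normexp (0.0401) and, with the mean of all probes, for Acta2 after TAC in WT (-0.57) and in NOS3-TG (-0.0674), Tek after TAC in NOS3-TG (-0.0143) and Eif2s3x between the sexes (0.0465), whose probes disagree. In other cases the cause was not tested.

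Normexp gave 2955 genes for TAC in WT, 1028 for TAC in NOS3-TG, 24 for genotype at baseline, 20 after TAC, 157 over both conditions, 42 for sex and 1 for sex by TAC. Without a filter there were 2872, 754, 30, 6, 129 and 32 for the first 6 of these, with more probes near background tested. With the filter on all 16 arrays there were 111 at baseline and 83 after TAC, and with the authors' values 108 and 72. Quantile normalization gave 78 for genotype after TAC. Array weights gave 3202 for TAC in NOS3-TG, 312 for genotype at baseline, 513 over both conditions and 743 for sex. An intensity trend gave 110 for genotype at baseline and 91 after TAC, and no sex term gave 19 after TAC. With the compared groups alone there were 1187 for TAC in NOS3-TG and 4 for genotype after TAC.

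Slide as a random block gave 83 for genotype after TAC, and as a fixed block 109 at baseline and 74 after TAC. The replicate numbers pair no animals, but NOS3-TG and WT arrays can be paired by slide and sex, and with these pairs as a fixed block there were 76, 60 and 317 at baseline, after TAC and over both conditions. Within slides 1 to 4, with 2 arrays per genotype or sex, there were 9, 1, 1 and 2 for genotype. For sex there were 4, 42, 9 and 4. Scan day as a block gave 2694 for TAC in WT and 756 in NOS3-TG, as the second day held TAC arrays alone. Without the 3 arrays with extreme shares above background there were 401 for TAC in NOS3-TG, 24 for genotype at baseline, 3 after TAC, 77 over both conditions and 24 for sex.

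Leaving out single arrays gave 2911 to 5024 genes for TAC in WT, 971 to 1780 for TAC in NOS3-TG, 26 to 85 for genotype at baseline, 2 to 61 after TAC, 0 to 1 for the interaction, 189 to 433 over both conditions, 67 to 550 for sex and 0 to 129 for sex by TAC.

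Over all comparisons camera called 122 lists with the preset correlation, 1 with an estimated one, and 41 by list means per array, 37 of them shared. It called 115 with quantile normalization (109 shared), 98 without the 3 arrays (93 shared) and 104 to 130 with single arrays left out. Of 73 called for genotype, interaction or sex, a slide block kept 71 and called 73. For extracellular matrix genes at baseline the mean was -0.033 without the 3 arrays and -0.0364 to 0.32 with single arrays left out, the lowest without NOS3-TG baseline replicate 2. For cell cycle genes after TAC between the genotypes it was -0.64 to -0.0238, and without WT TAC replicate 4, where it was highest, camera's direction turned.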

Other observations

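Some circadian clock genes changed with TAC. Of 19 clock genes 1 rose and 8 fell (1 and 9 adjusted over the list alone) in WT mice, with the activator Arntl higher (1.89) and the outputs Hlf (-1.89), Dbp (-1.49) and Ciart (-2.15) lower (camera adjusted p = 0.0264 and adjusted p = 0.495 with an estimated correlation). In NOS3-TG mice, of 19 clock genes 1 rose and 4 fell (2 and 8 adjusted over the list alone), with Hlf at -1.50 (camera adjusted p = 0.0151 and adjusted p = 0.565 with an estimated correlation). Between males and females of 19 clock genes 1 was higher and 2 lower (6 and 5 adjusted over the list alone), with Nr1d1 at 1.35 and Cry1 at -0.80 (camera adjusted p = 0.605, with median, mean and test differing in sign). The time of day of sampling was not used here. Of 16 adipocyte markers 6 fell (7 adjusted over the list alone) with TAC in WT, such as Car3 (-2.68) and Cidec (-2.60), with camera adjusted p = 0.0296 and adjusted p = 0.495 with an estimated correlation, and of 16 adipocyte markers 3 fell (4 adjusted over the list alone) in NOS3-TG (camera adjusted p = 0.0102 and adjusted p = 0.565 with an estimated correlation). With 1 array left out, the adjusted p was above 0.05 for Nr1d1 (0.0706) without WT TAC replicate 3, Cry1 (0.0857) without NOS3-TG TAC replicate 2, Car3 (0.102), Cidec (0.118) and the adipocyte markers list (0.083) without WT baseline replicate 1 and the adipocyte markers list (0.0911) without NOS3-TG baseline replicate 2.

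Markers of further tissues were checked for a mixed sample. With TAC in WT, of 16 atrial and conduction markers 1 rose and 3 fell (1 and 3 adjusted over the list alone), with camera adjusted p = 0.446. Of 11 skeletal muscle markers 2 rose and 4 fell (3 and 4 adjusted over the list alone), with camera adjusted p = 0.806, and of 11 erythroid markers 1 fell (1 adjusted over the list alone), with camera adjusted p = 0.549. Of 9 mesothelial markers 2 rose (2 adjusted over the list alone), with camera adjusted p = 0.187, and of 10 nerve and glial markers 2 rose and 4 fell (2 and 4 adjusted over the list alone), with camera adjusted p = 0.892. In NOS3-TG, of 16 atrial and conduction markers 1 rose and 2 fell (1 and 2 adjusted over the list alone), with camera adjusted p = 0.0317 and adjusted p = 0.669 with an estimated correlation. On leaving out 1 array, the adjusted p exceeded 0.05 for the atrial and conduction markers list (0.196) without NOS3-TG baseline replicate 2.

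Of the tests that follow, those on the genes of imprinted and host RNAs, and for the antioxidant genes the omission of 1 array, the means over all members and the position on the slide, and the splits within slides, were chosen after the result was seen, and the others before. Other splits of the arrays were counted over the 15508 genes with a value on every array. For TAC in WT, 1 of 35 splits, the real one, gave as many as its 4411 genes (highest other 1). TAC in NOS3-TG gave 1 of 35 (1831 genes, highest other 3). No slide held both conditions, so slide effects are not excluded. Chance is not excluded for genotype over both conditions (2 of 100, 328 genes, another gave 427). Nor is it for sex (2 of 100, 209 genes, another gave 291). Nor is chance excluded for genotype after TAC (3 of 35, 44 genes, highest other 141) or, at an unadjusted p under 0.05, for the genotype-by-TAC (26 of 100, 1157 genes, highest other 3164) and sex-by-TAC interactions (7 of 100, 1752 genes, highest other 2971). For genotype at baseline this count cannot exclude it either: 2 of 35 splits gave as many as its 66 genes. The other was slide 1 against slide 4 with 668, which points to differences between slides. The 18 splits that divide each slide evenly are too few for a share under 0.05, and the highest other gave 4 at baseline and 98 after TAC. A slide block gave 109 at baseline, and slides 1 and 4 alone 9 and 2.

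The 12 antioxidant genes called higher in NOS3-TG hearts over both conditions, 8 outside glutathione transferases, had a mean difference of 0.81, raised by selection. In 4 of them all 8 NOS3-TG arrays lay above all 8 WT arrays. Over all 49 measured members of the list, fixed before the data, the mean was 0.26 ± 0.05 (SE). It was at least 0.23 with any array left out, which argues against 1 array as the cause. More macrophages are argued against too, as it was 0.24 ± 0.08 with each array's macrophage score in the fit (0.94 ± 0.12 over the 12 called genes). Position on the slide and genotype cannot be told apart, since 4 of 4 slides held NOS3-TG arrays at positions 1 and 2. A response to the overexpressed enzyme stays open, as untested.

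Snhg11, Snrpn, Snurf, Snhg14 and Peg3, imprinted transcripts or host genes of small nucleolar RNAs, were higher in NOS3-TG hearts over both conditions (Snhg11 at least 9.87-fold, the others by 1.60, 1.36, 1.72 and 2.24) and fell with TAC in those hearts, to log2 changes of -2.33, -1.47, -1.50, -1.51 and -2.04 (for Peg3 with adjusted p = 0.0821 without NOS3-TG TAC replicate 4, and the other calls held without any array). In WT hearts, where no array showed Snhg11 above background, the others changed by -1.04, -0.44, -1.23 and -0.58 with TAC (Peg3 above background on 2 TAC arrays), of which Snrpn (adjusted p = 0.00264) and Snhg14 (adjusted p = 0.0164) passed. The tables argue against neighbours of 1 insertion site, since they lie at 3 places more than 30 tested genes apart or on other chromosomes. That distance was set after the positions were seen (an earlier one of 100 annotated genes gave 4 places). The nerve and glial score differed by -0.05 ± 0.12 (SE, upper 95% bound 0.22). A mean over markers can miss a small amount, so more nerve tissue stays open. Whether the probes bind the transgene's RNA stays open: the fall with TAC exceeded that of Nos3 (mean difference -1.29, two-sided exact permutation p = 0.0286, the smallest possible over 70 arrangements), but the genes were picked after these values were seen. An effect of the transgene on these genes stays open, as untested.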
